A study of Mus musculus with 8 samples.

How the data were processed

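Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was profiled by CUT&Tag in mouse embryonic stem cells. CUT&Tag tethers a transposase to an antibody-bound chromatin mark, so that tagged fragments can be sequenced. The 8 libraries formed 4 groups of 2: naive and formative cells, each wild type (WT) or lacking both MLL3 and MLL4 (DKO). MLL3 and MLL4, encoded by Kmt2c and Kmt2d, are H3K4 methyltransferases known for their role at enhancers. Per the labels, formative cells were taken 63 hours after LIF2i withdrawal, the WT cells were the R1 line, and no line is named for the DKO cells. Replicates were cultured and prepared independently, per the series design text.

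Per the submitters' processing notes, the tools were Trim Galore, Bowtie2, SEACR, DiffBind and deepTools, and the genome build was mm10. Their versions, roles and order are not given in the sources used here. The authors deposited 1 table of 112137 regions by 47 columns. The 4 H3K27ac columns are the authors' pooled log2 values, log2(value + 1), with 1 value per group and so with no SD or n. Scaling between groups is not stated. The log2 fold columns deposited for H3K27ac equalled differences of those columns. The deposited DiffBind columns give a log2 fold, a p-value and a Benjamini-Hochberg adjusted p-value for formative against naive WT, the only replicated test in the table. They also give other descriptors, such as region width and distance to the nearest transcription start site (TSS), as deposited by the authors. The deposited log2 folds for H3K4me1 and for RNA of the nearest gene come from libraries outside this series and were used only as comparison columns. RNA folds were present for 9781 genes, and every region of a gene carried the same fold to within rounding. The 12 columns of H3K4me1 and RNA levels per sample group were not used, nor were 6 RNA fold columns of other genotypes.

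The unit was checked on the values. In a regression of log2 value on DiffBind concentration and log2 width, the width exponent was -1.99 for naive WT and -2.01 for formative WT. A sum divided by width 2 times would give an exponent near these values. Reported differences are therefore ratios between groups within a region. Where regions are ranked by mean signal, for the filter and for loess offsets, the level with both divisions by width undone was used. The rule for named regions used the deposited level, except for list regions in comparisons without a p-value. Total reads per library are not in the columns used, so the depth is unknown and no counting interval is given.

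The designs fixed before the data were examined called for tests across 8 libraries. Pooled columns do not allow these, so 4 of the 5 comparisons are described by size alone: a region was called higher or lower at an absolute log2 fold of at least 1 (2-fold), with no p-value. The main set holds the 105643 regions above 0 in all 4 groups. The 6494 others were listed at 0 in at least 1 group. For formative against naive WT, the authors' DiffBind adjusted p under 0.05 was used. Promoters are the regions the file labels as such, and distal regions are all others. For 14 gene lists fixed beforehand, a gene received the regions within 100 kb of its TSS as annotated in the file. Some lists share genes, so their values are not separate findings. Socs3, Stat3, Klf4, Klf5, Tfcp2l1 and Gbx2 are in both the naive pluripotency and LIF/STAT3 lists. The Wnt/beta-catenin list shares T, Wnt3 and Cdx1 with the primed and mesendoderm list and Lef1 with the formative list. Eomes and Hand1 are in both the primed and trophoblast lists. The median over a gene's regions was taken, then the median over genes. Its percentile among 10000 random lists of the same size, matched on concentration and number of regions, describes these values and is not a test. Correlations are across regions or genes, which are not independent replicates.

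The rule for named regions was fixed beforehand. Per comparison it took, among regions past the threshold and above the median of mean log2 value, the 8 with the largest positive and the 8 with the largest negative fold, 1 per gene. It added up to 4 genes per list with the smallest adjusted p, and all regions of Kmt2c and Kmt2d. Its condition on single libraries could not be applied, a known gene within 100 kb was required, and where no p existed the largest absolute fold in a list replaced it. List regions chosen in that way were also required to lie above the median of the level with both divisions by width undone. That requirement was not part of the fixed rule. The gene assigned to a region is the one with the nearest TSS in the file, so an intronic region can lie in another gene. Gene medians given for single list members were chosen after their values were seen. Because the level falls with width, the rule selected narrow regions, with a median width of 450 bases. A second set was therefore added after the values were seen, using the level with both divisions by width undone. Its regions had a median width of 1653.5 bases, and of its 80 regions 4 were also named by the fixed rule. The report names such regions as added.

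Alternatives covered scaling, filter, pseudocount, threshold, promoter window and distance to TSS. The 6 alternative scalings were quantile normalization, the sum over all regions, promoters, loess offsets, median centring and value times width. The sum was taken over the deposited values, with the divisions by width not undone. Narrow regions therefore weigh more in it, and it is not a scaling to total reads. Value times width cancels between groups within a region, except through the pseudocount, so it could hardly change a sign. Sequence composition came from the reference of the same build. Code for counting was tested on simulated values over 105643 regions for naive DKO against naive WT. It recovered 100 of 100 regions changed by 2.0 on the log2 scale and 100 of 100 changed by 1.3. For formative DKO against formative WT it recovered 100 of 100 and 96 of 100. The simulated noise was far smaller than the spread of the real folds, whose quartiles were -1.07 and 0.75 for naive DKO against WT. These recoveries therefore check the code and not the sensitivity of the size rule on these data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, pysam 0.24.0 and matplotlib 3.10.9 were used.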

Results

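H3K27ac was measured over 112137 regions in naive and formative mouse embryonic stem cells, WT or DKO for MLL3 and MLL4, with 2 libraries in each of 4 groups. Values are the authors' pooled log2 values per group, with no SD or n, so no difference involving DKO cells has a replicate check. Coordinates are mm10. The design addresses how H3K27ac changes between the naive and formative states, and how it differs without MLL3 and MLL4.

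The knocked out genes come first. Kmt2c, encoding MLL3, had 3 intronic regions on chromosome 5, all lower in DKO than in WT by the pooled values. The region at 25486550 to 25487638 was at -0.68 in naive and -0.88 in formative cells, and that at 25383202 to 25384046 at -0.89 and -0.74. The narrow region at 25478535 to 25479038 was at -1.23 in naive and -6.72 in formative cells, where the pooled log2 value of formative DKO was only 1.82. Kmt2d, encoding MLL4, had 5 regions, whose log2 DKO against WT ran from -0.32 to 1.10 in naive and from -0.77 to 0.91 in formative cells. Its promoter on chromosome 15, 98871415 to 98872665, was at 0.34 and 0.91. In the authors' deposited table, RNA of Kmt2c was at -1.15 and -0.91 and RNA of Kmt2d at -0.72 and -0.84 in naive and formative cells, log2 DKO against WT. The parts deleted are not given in the sources used here, so these regions do not check the knockout itself.

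Formative and naive WT cells were compared first, by the authors' test. Regions fell at most naive pluripotency genes and rose at 12 of 25 formative ones without falling at any other region of the same gene. In the authors' deposited table, 41030 regions changed at a DiffBind adjusted p under 0.05, of which 23353 rose and 17677 fell. The median log2 fold in the authors' deposited table was 3.04 for rising and -1.98 for falling regions. At promoters 589 regions rose and 1433 fell in the authors' deposited table, against 22764 and 16244 elsewhere. In the quintile of regions with the lowest WT concentration, 8490 rose and 440 fell in the authors' deposited table. In the highest quintile 3429 rose and 10046 fell in the authors' deposited table.

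All 24 genes of the naive pluripotency list had a region that changed in WT. They had 247 regions, of which 155 fell and 11 rose. Of all regions 36.6% were called, so a gene with many regions is likely to have a call. The same limit holds for the gene counts of the other lists. In the naive pluripotency list, regions only fell at 17 of the 24 genes, only rose at 1 and went both ways at 6. Adjusted over the list alone these were 16, 1 and 7. The list median was -2.41, at percentile 0 among matched random lists, and from -3.19 to -2.12 over 6 alternative scalings. List medians and percentiles use the pooled values and are not tests. A fold with an adjusted p is that of 1 region, the one with the smallest p for a list gene, and other regions of the gene can differ. Jam2 fell by 4.98 at an intergenic region on chromosome 16, 84768234 to 84775267 (DiffBind adjusted p = 2.82e-130), in the authors' deposited table. Tet2, encoding a 5-methylcytosine dioxygenase, fell by 4.29 at an intronic region (DiffBind adjusted p = 9.93e-130) in the authors' deposited table. Klf5, a pluripotency transcription factor, fell by 3.95 at an intergenic region on chromosome 14 (DiffBind adjusted p = 8.13e-120), per the authors' deposited table. The promoter of Zfp42, a marker of naive cells on chromosome 8, fell by 4.10 (DiffBind adjusted p = 2.92e-91) in the authors' deposited table.

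Of 25 formative pluripotency genes with a region, 12 had regions that only rose, 7 only fell, 2 went both ways and 4 had none called. Adjusted over the list alone these were 13, 7, 2 and 3. Its median was 1.31, at percentile 99.95, but 0.83 after quantile normalization and 0.37 with loess offsets, where 9 genes were at least 2-fold higher and 6 lower, against 13 and 4. Car4 rose by 3.61 at an intergenic region on chromosome 11, 84942416 to 84947449 (DiffBind adjusted p = 2.78e-17), in the authors' deposited table. A region of Foxd3 fell by 3.56 (DiffBind adjusted p = 1.05e-35) and a region of Nkx6-3 on chromosome 8 fell by 4.04 (DiffBind adjusted p = 2.32e-41), in the authors' deposited table. Of 9 Nkx6-3 regions 3 fell, with a pooled median of 0.50. Pou3f1, a formative transcription factor, was chosen after its values were seen and had a pooled median of 2.31, with 4 regions that rose by the authors' test. Counts adjusted over the list alone equalled the counts given for all other lists except housekeeping.

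Of 15 core pluripotency genes, regions only fell at 8, only rose at 2 and went both ways at 5. The Sox2 promoter fell by 4.77 (DiffBind adjusted p = 5.72e-35) and a region upstream of Pou5f1 fell by 3.14 (DiffBind adjusted p = 3.51e-28), in the authors' deposited table. RNA of these genes was at -0.92 and -0.41 in the authors' deposited table. Of 15 LIF/STAT3 response genes, regions only fell at 8, only rose at 1 and went both ways at 6. A region of Klf4 fell by 5.16 (DiffBind adjusted p = 4.63e-64) and one of Sgk1 fell by 4.16 (DiffBind adjusted p = 8.2e-101) in the authors' deposited table. Of 22 Sgk1 regions 7 fell and 3 rose by the authors' test, with a pooled median of -0.05.

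Of 14 primed and mesendoderm genes with a region, 7 had regions that only rose, 1 had both and 6 had none called. Wnt3 rose by 2.22 (DiffBind adjusted p = 5.48e-08) and Cer1 by 5.32 (DiffBind adjusted p = 2.24e-07), while Gsc fell by 3.31 at 1 of its regions, of which 2 fell and 1 rose (DiffBind adjusted p = 1.09e-08), in the authors' deposited table. Of 14 primitive endoderm genes, 8 had regions that only rose, 2 had both and 4 had none called. Lamb1, a laminin subunit, rose by 7.81 at an intronic region (DiffBind adjusted p = 1.31e-10) in the authors' deposited table. Of 16 Wnt/beta-catenin response genes, regions only rose at 10, only fell at 2 and went both ways at 2, and 2 genes had none called. A region of Nkd1 on chromosome 8 rose by 5.21 (DiffBind adjusted p = 4.15e-09) and Notum fell by 3.34 (DiffBind adjusted p = 4.66e-23) in the authors' deposited table. Trophoblast genes split, with 3 that only rose, 2 that only fell, 2 with both and 5 with none called among 12. Krt18 rose by 3.27 (DiffBind adjusted p = 2.26e-16) and Tfap2c fell by 3.67 (DiffBind adjusted p = 3.51e-28) in the authors' deposited table.

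Of 16 ERK response genes, regions only rose at 6, only fell at 1 and went both ways at 7, and 2 genes had none called. Among 23 genes of the H3K4 methylation and H3K27 acetylation machinery, regions only fell at 11, only rose at 2 and went both ways at 5, and 5 genes had none called. Paxip1, which encodes a partner of MLL3 and MLL4, fell by 5.89 at an intergenic region (DiffBind adjusted p = 1.22e-83), 1 of 5 that fell among its 19, in the authors' deposited table. Of 19 housekeeping genes 8 only fell, 2 only rose, 4 had both and 5 had none called. Adjusted over the list alone, 9 housekeeping genes only fell and 3 had both. The fibroblast feeder list, which marks cells that could be carried over in culture, had 3 that only rose and 4 that only fell and 2 with none called among 9 genes. Of 10 neural and ectoderm genes 3 only rose, 1 had both and 6 had none called. Nes, a marker of neural progenitors, rose by 1.72 at an intergenic region (DiffBind adjusted p = 0.00458) in the authors' deposited table. Sox1, the neural gene with both, had 1 region that rose and 2 that fell by the authors' test. Of 8 germline and 2-cell-like genes 3 only rose, 3 only fell, 1 had both and 1 had none called. Tcstv3, which only fell, had 1 region in the main set, and 46.6% of that region was telomere repeat.

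Among regions taken by the fixed rule, an intronic region assigned to Trp53bp1 on chromosome 2, 121222846 to 121223488, rose by 6.73 (DiffBind adjusted p = 2.27e-06) in the authors' deposited table. Wider regions, added after the values were seen, included an intronic region assigned to Zfp608 on chromosome 18, 54909797 to 54912035, that rose by 6.91 (DiffBind adjusted p = 2.96e-21) in the authors' deposited table. An added intergenic region near Cobl on chromosome 11, 12520804 to 12523591, fell by 7.97 (DiffBind adjusted p = 1.62e-60) in the authors' deposited table.

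The median change of state was smaller in DKO than in WT over regions called in WT, a difference that was not tested. By the pooled values, 17589 regions were at least 2-fold higher and 18920 at least 2-fold lower in formative than in naive DKO cells, with a median of -0.07. The higher share of these was 48.2%, but 35.9% among regions above the median of mean signal. That share was 56.5% after scaling to the sum over all regions and 56.6% after scaling to promoters. The median was 0.08 after scaling to the sum over all regions or to promoters. The pooled WT values gave 40278 and 19957, with a median of 0.48. Over regions that rose in WT by the authors' test, the WT median was 2.59 and the DKO median 0.31. In DKO 25.9% of them were at least 2-fold higher as well and 12.1% at least 2-fold lower. Over regions that fell in WT, the DKO median was -0.60, or 29.7% of the WT median. In DKO 31.9% of these were at least 2-fold lower and 4.25% at least 2-fold higher. Over all regions 16.6% were at least 2-fold higher and 17.9% at least 2-fold lower in DKO. The ratios of DKO over WT medians were 0.118 for rising and 0.297 for falling regions. They were 0.153 and 0.185 with quantile normalization, 0.200 and 0.199 with loess offsets, and 0.249 and 0.605 near genes chosen by RNA. The regions called in WT were picked on the WT libraries, which enlarges the WT folds. Near genes picked instead by RNA at least 4-fold higher in formative WT in the authors' deposited table, the medians were 1.64 in WT and 0.41 in DKO over 3056 regions. Near genes with RNA at least 4-fold lower they were -0.98 and -0.59 over 1308 regions. The sets chosen by RNA were examined in the main scaling alone.

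**Figure D1:**
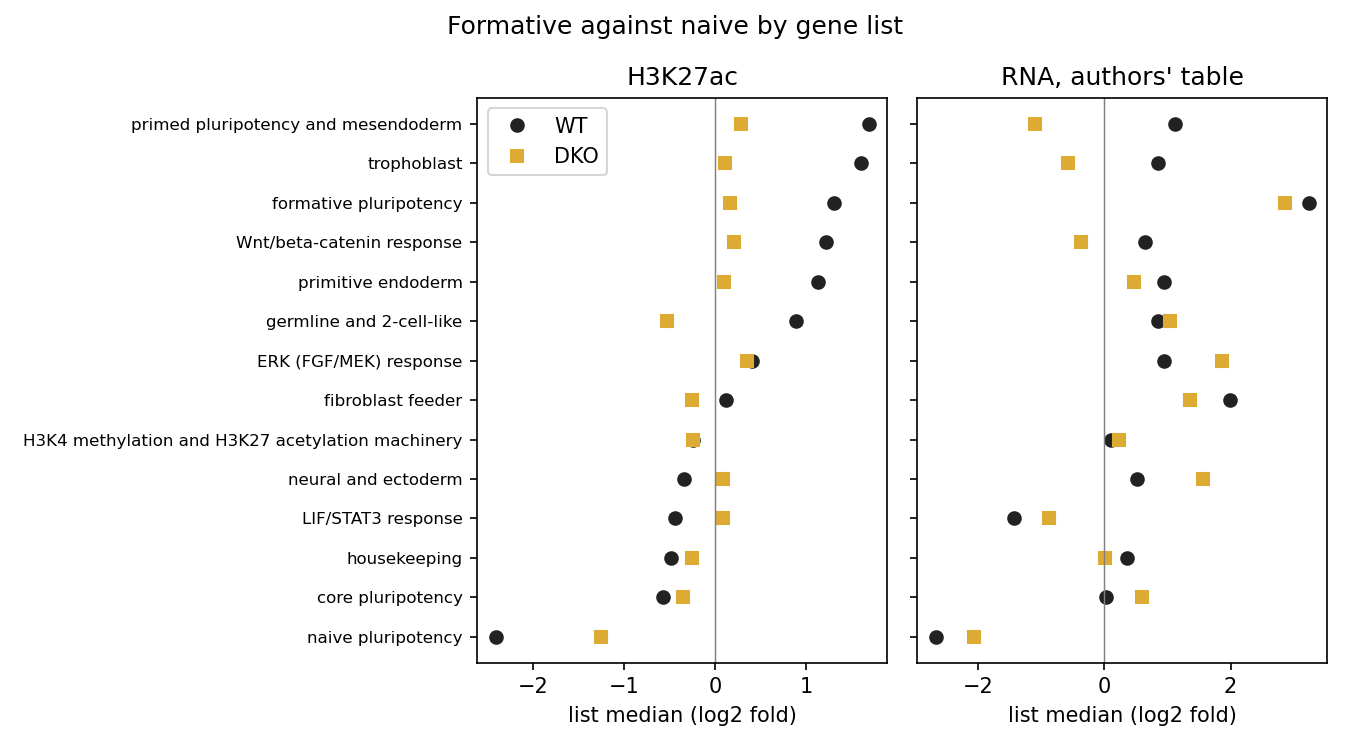
Median log2 fold of formative against naive cells for 14 gene lists, with H3K27ac on the left and RNA from the authors' deposited table on the right; circles are WT and squares DKO, with no error bars because the columns are pooled. The formative pluripotency list lay at 1.31 in WT and 0.16 in DKO for H3K27ac, or 0.37 and 0.19 with loess offsets, and at 3.24 and 2.87 for RNA, while in WT the primed and mesendoderm list (1.69) lay at 0.06 with loess offsets, the trophoblast list (1.61) lay below 0 with loess offsets, ERK (0.41) with loess offsets or median centring, the machinery list (-0.24) above 0 after scaling to promoters, and the fibroblast list (0.12) below 0 in 4 scalings.

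Naive pluripotency genes were lower in formative than in naive DKO cells, with a list median of -1.26 and 16 of 24 genes at least 2-fold lower. In DKO all 14 list medians had the same sign in all 6 alternative scalings, of which value times width could hardly change one. Genes named by their median here and below were chosen after their values were seen. Zfp42 had a median of -1.68 in DKO and -3.47 in WT, and Jam2 -2.08 and -4.32. For Nanog, a pluripotency transcription factor, the values were -1.39 and -1.33. Formative pluripotency genes had a DKO median of 0.16, with 6 genes at least 2-fold higher and 4 at least 2-fold lower. With loess offsets the medians of this list were 0.37 in WT and 0.19 in DKO. Pou3f1 was at 1.93 and Lef1 at 1.62 in DKO, while Sall2 was at -0.17 and Grhl2 at -0.73 against WT medians of 2.09 and 1.99. RNA of the formative list was higher in formative cells of both genotypes, with medians of 3.24 in WT and 2.87 in DKO in the authors' deposited table. RNA of the primed and mesendoderm list was at 1.12 in WT and -1.10 in DKO in the authors' deposited table. Its H3K27ac medians were 1.69 and 0.29, but 0.06 and 0.21 with loess offsets. Wnt3 had RNA at 4.94 in WT and -1.21 in DKO in the authors' deposited table. ERK response genes had H3K27ac medians of 0.41 in WT, which was -0.29 with loess offsets and -0.07 with median centring, and 0.35 in DKO. Spry4, an ERK feedback inhibitor, was at -0.47 in WT and 2.22 in DKO. The other list medians in DKO were 0.21 for Wnt/beta-catenin, 0.11 for trophoblast, 0.10 for primitive endoderm, 0.09 for neural and 0.08 for LIF/STAT3. Below 0 were core pluripotency at -0.35, housekeeping at -0.25, fibroblast at -0.25, the machinery at -0.24 and germline at -0.53. By the fixed rule, a narrow intronic region of Hacd1 on chromosome 2, 14048578 to 14048998, was at 8.20. Among added wider regions, an intronic region nearest to Tmcc3 on chromosome 10, 94544835 to 94546901, was at 4.00, and an intergenic region near Grhl3 on chromosome 4, 135599344 to 135600769, was at -4.38.

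In naive cells, the median of DKO against WT was 0.58 at promoters and -0.15 at distal regions, a difference of -0.73. Intergenic regions lay at -0.68, with 41.6% at least 2-fold lower. In all, 20335 regions were at least 2-fold higher and 27829 lower, so 42.2% of them were higher. That share was 20.8% after scaling to promoters and 52.4% after scaling to the sum over all regions. Over all regions the median was -0.10, against -0.68 after scaling to promoters, 0.08 after quantile normalization and 0.12 after scaling to the sum. The LIF/STAT3 list had a median of -0.81 (-1.39 to -0.59 over 6 alternative scalings), at percentile 0.47. Of its 15 genes 6 were at least 2-fold lower and 1 higher. These counts were 3 and 2 after quantile normalization and 8 and 1 after scaling to promoters. Lifr and Osmr, which encode cytokine receptor subunits, had medians of -1.58 and -1.58, and the higher gene was Socs3 at 1.67. RNA of the list had a median of -0.08 over 13 genes in the authors' deposited table. Naive pluripotency genes had a median of -0.32 (-0.90 to -0.10), with 8 of 24 at least 2-fold lower and 1 higher, among them Nr5a2 at -2.23, and Klf2 at -1.74 and Zfp42 at -1.35, which lie on chromosome 8 with its lower median. RNA of these 3 genes was at -0.76, -0.77 and -0.83 in the authors' deposited table. Formative genes were at -0.27 (-0.85 to -0.05), with 8 of 24 at least 2-fold lower and 3 higher. Among the lower ones were Otx2 at -2.27 and Dnmt3b at -1.61. Medians of the fibroblast (-1.05), neural (-0.82), primed and mesendoderm (-0.63), ERK (-0.45) and core (-0.33) lists were below 0 in all 6 alternative scalings too. Their values closest to 0 over these scalings were -0.77, -0.50, -0.34, -0.23 and -0.06, in that order, and all 5 were lowest after scaling to promoters. Their percentiles were 3.7, 7.4, 4.41, 5.08 and 18.9, in the same order. Housekeeping genes were at 0.49, at percentile 98.95, but at -0.09 after scaling to promoters. The machinery list was at 0.13 and at -0.44 after scaling to promoters. Primitive endoderm (-0.02), trophoblast (-0.04) and germline (-0.13) medians changed sign with scaling, and the Wnt/beta-catenin median of 0.00 was -0.57 after scaling to promoters. Trophoblast keratin Krt18 was at 3.87, with RNA at 2.95 in the authors' deposited table. In the trophoblast list 1 gene, Krt18, was at least 2-fold higher and 2 were lower. Keratins Krt7 and Krt8 were at -0.94 and 0.53, with RNA at 3.29 and 1.71 in the authors' deposited table. By the fixed rule, the promoter of Cep128 on chromosome 12, 91384209 to 91384849, was at 7.71. Added wider regions included an intergenic region nearest to Lix1 on chromosome 17, 17495283 to 17499308, at -5.73. RNA of Lix1 was at -4.27 in the authors' deposited table.

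**Figure D2:**
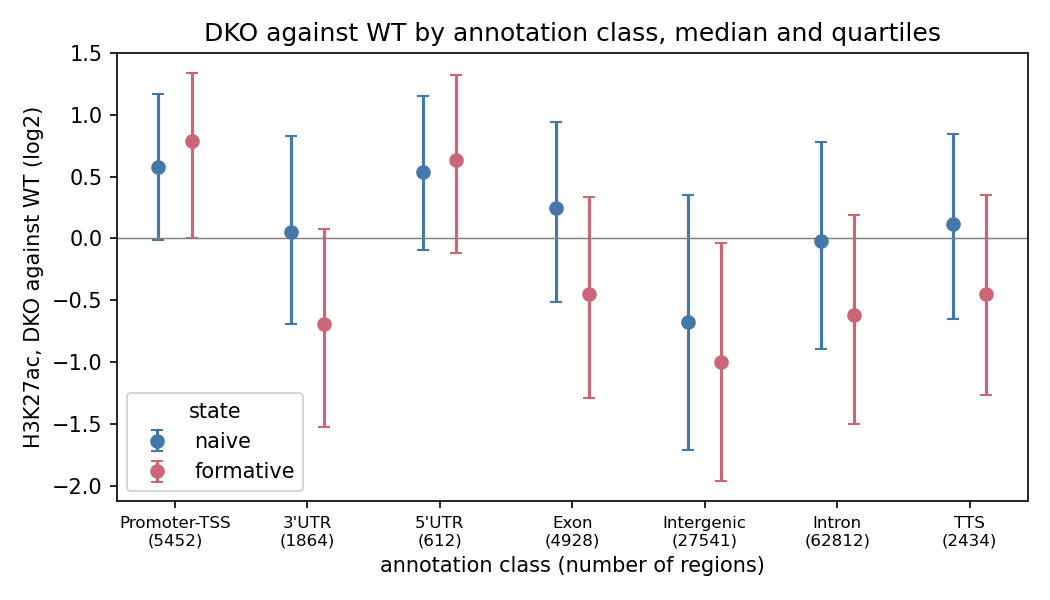
Log2 H3K27ac of DKO against WT by annotation class, with points for medians and bars for quartiles over regions, naive in blue and formative in red. Promoter medians were 0.58 and 0.79, which scaling to promoters brings to about 0 by construction, and 41.6% of intergenic regions were at least 2-fold lower in naive DKO.

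In formative cells, the promoter median of DKO against WT was 0.79 and the distal median -0.69, a difference of -1.48, which was -0.66 with loess offsets. In the quintile of regions with the highest naive WT concentration the distal median was 0.14, but -0.15 with loess offsets, -0.58 after scaling to promoters, 0.62 by sum, 0.77 after median centring and 1.14 after quantile normalization. In all, 41479 regions were at least 2-fold lower and 11873 higher, so 22.3% of them were higher. That share was 52.9% after quantile normalization, 51.7% with loess offsets, 48.7% after median centring, 42.1% after scaling to the sum, 6.06% after scaling to promoters and 51.2% among regions above the median of mean signal. Over all regions the median was -0.63, against 0.10, 0.04, -0.15 and -1.35 after quantile, loess, sum and promoter scaling. Of 24 formative pluripotency genes, 12 were at least 2-fold lower and 0 at least 2-fold higher, against 5 and 4 after quantile normalization, 6 and 2 with loess offsets and 19 and 0 after scaling to promoters. The list median was at percentile 2.58, and was -0.17 after quantile normalization, -0.19 with loess offsets and -1.72 after scaling to promoters. Dnmt3b was at -2.29, Dnmt3a at -1.22 and Pou3f1 at -1.17. RNA of Dnmt3a was at -0.86 and that of Pou3f1 at 0.47 in the authors' deposited table, with none for Dnmt3b. The primed and mesendoderm list was at -1.52, at percentile 1.97, but at -0.24 with loess offsets and -0.83 after quantile normalization. It included T (Brachyury) at -2.67, Lefty1 at -2.17, Hand1 at -1.88 and Wnt3 at -1.26. RNA was at -3.23 for T, -1.52 for Lefty1, 1.21 for Hand1 and -2.04 for Wnt3 in the authors' deposited table. Naive pluripotency genes had a median of 0.12, which was -0.60 after scaling to promoters, with 6 higher and 4 lower by at least 2-fold. These counts were 12 and 3 after quantile normalization and 1 and 10 after scaling to promoters. Among the 6 higher genes Spp1 was at 1.99 and Jam2 at 1.68, with RNA at 1.89 and 0.34 in the authors' deposited table. The 4 lower genes were Nr5a2 at -1.97, Tcl1 at -1.88, Gbx2 at -1.85 and Fbxo15 at -1.19. RNA was at -0.02 for Nr5a2, 3.44 for Gbx2 and -0.04 for Fbxo15 in the authors' deposited table, with none for Tcl1. Housekeeping genes were at 0.72, at percentile 99.95, but at 1.57 after quantile normalization and at 0.00 after scaling to promoters. Fibroblast (-1.18), germline (-1.05) and Wnt/beta-catenin (-0.77) medians were below 0 in all 6 alternative scalings, at -0.37, -0.35 and -0.05 after quantile normalization. Among matched random lists they lay only at percentiles 22.0, 31.3 and 28.9. Medians of LIF/STAT3 (0.34), the machinery (0.16) and ERK (0.01) lay below 0 after scaling to promoters. Neural (-0.72), trophoblast (-0.69), primitive endoderm (-0.56) and core (-0.17) medians lay above 0 in at least 1 scaling. Added wider regions included an intronic region of Itpr1 on chromosome 6, which has a lower median, 108259508 to 108261413, at -4.50.

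Naive and formative comparisons of DKO with WT share no libraries. Regions at least 2-fold lower in both numbered 14869, against 10926.6 for independent lists, and regions higher in both 2935, against 2285.41. Across regions the folds of the 2 states had a Pearson correlation of 0.133 and a Spearman correlation of 0.178. H3K4me1 in the authors' deposited table, DKO against WT, had promoter medians of 0.68 in naive and 0.66 in formative cells, and distal medians of -0.35 and -0.05. H3K27ac and RNA folds were compared across 9600 genes with RNA from the authors' deposited table. Pearson and Spearman correlations were 0.363 and 0.338 for the change of state in WT, and 0.239 and 0.232 in DKO. For DKO against WT they were 0.270 and 0.262 in naive and 0.162 and 0.142 in formative cells. Regions and genes are not independent replicates.

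The difference of the changes of state, DKO minus WT, was not testable. It was at least 1 on the log2 scale in 20567 regions and at most -1 in 38350, with a median of -0.39. The higher share of 34.9% was 53.4% after quantile normalization, 50.5% with loess offsets, 48.1% after median centring and 51.7% among regions above the median of mean signal. The median was 0.16 after quantile normalization, -0.12 after scaling to the sum and -0.53 after scaling to promoters. Naive pluripotency genes had a median of 0.89, at percentile 99.99, and from 0.75 to 1.85 over 6 alternative scalings. Formative genes had one of -0.91, at percentile 1.54, which was 0.10 with loess offsets. LIF/STAT3 (0.69), ERK (0.36), core (0.35) and housekeeping (0.35) medians were above 0, and primed and mesendoderm (-1.37), Wnt/beta-catenin (-1.03) and germline (-0.96) medians below 0, in all 6. With loess offsets the last 3 were -0.52, -0.54 and -0.36. The first 4 were 1.13, 0.76, 1.28 and 0.95 after quantile normalization, but 0.55, 0.22, 0.21 and 0.21 after scaling to promoters. With loess offsets core was at 0.23 and housekeeping at 0.15. Percentiles were 99.58, 99.57, 84.65 and 87.1 for the first 4, and 2.39, 4.73 and 29.52 for the last 3. Trophoblast (-1.02), neural (-0.47), primitive endoderm (-0.42), machinery (0.13) and fibroblast (-0.07) medians changed sign in at least 1. List regions given here had the largest absolute fold of their gene above the median of mean signal, a level that the fixed rule did not set. The region so chosen was at 4.04 for Zfp42, on chromosome 8, and at 3.42 for Esrrb, whose medians over all regions were 1.35 and 1.15. For Tfcp2l1 it was at 3.73, but the median over its 32 regions was -0.24. For Mixl1, a mesendoderm factor, it was at -2.83 with a median of -1.92, and for Krt18 at -4.40 with a median of -3.37. By the fixed rule, the most negative was a narrow intronic region nearest to Smim19 on chromosome 8, 22510613 to 22511015, at -10.97. Among added wider regions, one near Tmem64 on chromosome 4, 15251457 to 15253749, was at 6.81, and one near Ccdc141 on chromosome 2, 77171183 to 77172216, at -6.88.

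DKO against WT also differed by chromosome. Medians on chromosomes 6 and 8 were -0.48 and -0.45 in naive cells, and -1.01 and -1.15 in formative cells, below those of the other autosomes, while chromosome X was at -0.77 and -0.71. Promoter medians on chromosomes 6 and 8 were 0.18 and 0.08 in naive and 0.39 and 0.12 in formative cells. Genes named above that lie on these chromosomes include Itpr1 (chromosome 6) and Klf2, Zfp42, Nkx6-3, Nkd1 and Smim19 (chromosome 8).

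**Figure D3:**
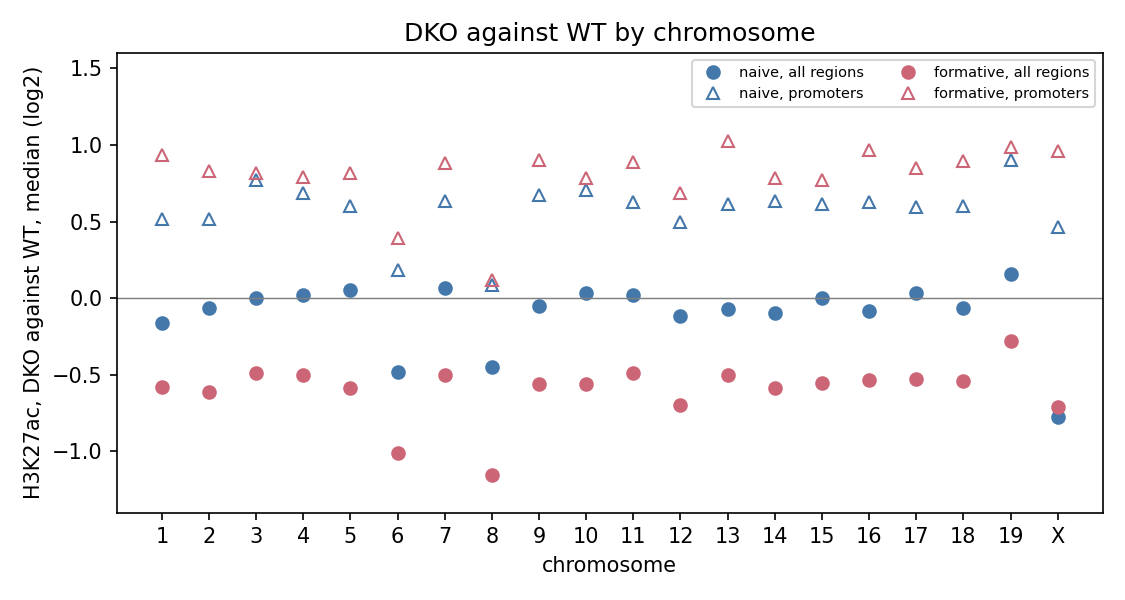
Median log2 H3K27ac of DKO against WT by chromosome, circles for all regions and open triangles for promoters, naive in blue and formative in red; chromosome Y is left out. Chromosomes 6 and 8 lie lowest among autosomes, at -1.01 and -1.15 for all regions in formative cells.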

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

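The tests of signal level, of the distal median, of chromosome copies and of telomere repeats were chosen after the result was seen. Of the gene lists, 2 had medians of opposite sign between groups, by at least 1 on the log2 scale, and neither difference was tested. For the LIF/STAT3 response list, DKO against WT was at -0.81 in naive and 0.34 in formative cells, a difference of 1.16. The formative value was -0.38 after scaling to promoters. For the germline and 2-cell-like list, with 8 genes, the change of state was at 0.89 in WT and -0.53 in DKO, a difference of -1.42. The values were 0.58 and -0.28 with quantile normalization, 0.58 and -0.23 with loess offsets and 0.41 and -0.46 after median centring, gaps of under 1 on the log2 scale. In the main scaling the WT value was at percentile 48.98 among matched random lists, whose median was 0.90. The DKO value was at percentile 3.63. The median difference per gene, -0.96, was at percentile 29.52.

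Distal regions lay below promoters in formative DKO against WT by -1.48. Within deciles of GC content the difference was -1.57, and within quintiles of WT concentration -1.12, and loess offsets against mean signal left -0.66, which argues against either as the whole cause but leaves signal level open for part of it. Among the top quintile of regions by naive WT concentration, which formative WT did not choose, it was -0.95, which argues against chance in calling regions as the whole cause of the gap. An offset shared by all regions of a group cannot change this difference. Of the scalings that can, quantile normalization gave -0.70 and loess offsets -0.77. In that quintile the distal median was 0.14, but -0.15 with loess offsets, -0.58 after scaling to promoters and 1.14 after quantile normalization, so whether the distal deficit comes from regions called because formative WT was high by chance cannot be told apart from a true deficit while the scaling is unknown. A genotype effect at enhancers stays open and untested, since no replicate values exist.

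Across chromosomes 6 and 8, all 28 windows of 10 Mb of DKO against WT lay below the genome median in both states, against 107 of 224 windows of other autosomes in naive and 85 in formative cells. Promoters shifted by -0.49 and -0.64 and all regions by -0.44 and -0.54, which is consistent with more copies of both chromosomes in the WT than in the DKO libraries, for which log2 of 2 over 3 is -0.58. Extra weak regions do not account for it, since the shift was -0.37 in naive cells in the top quintile by WT concentration. In libraries outside this series, RNA on chromosomes 6 and 8 was at 0.03 and -0.08 in naive and 0.18 and -0.05 in formative cells, and chromosomes 14 and 17 had naive RNA at -0.22 and -0.26. Naive H3K4me1 there was at -0.31 on chromosome 6, against -0.31 to -0.15 on autosomes other than 6, 8, 14 and 17, and at -0.57, -0.55 and -0.56 on chromosomes 8, 14 and 17, while formative H3K4me1 was at -0.11, -0.20, -0.22 and -0.20 on chromosomes 6, 8, 14 and 17 and at -0.01 to 0.14 on those others, so a difference between cell lines or passages stays open.

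Regions rich in the telomere repeat, 81 on 20 chromosomes, had folds with a narrower spread than other regions. Their medians were -1.35 for the change of state in WT and -0.67 in DKO. One candidate explanation is a shared pool of repeat reads placed at several positions. The largest ratio of their interquartile range to that of other regions of like concentration was 0.394, between the bounds set, so it cannot be told apart from a spread of local values. The repeat share of these regions ran from 10.1% to 93.0%, so the ratio mixes regions with little and with much repeat. No biological explanation was tested.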

How the results depend on the processing

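Median centring, an absolute log2 fold of at least 2, pooled WT values, the set of regions above 0 for the authors' test, promoters within 1 kb, selection by RNA, value times width and leaving out chromosomes 6 and 8 were chosen after seeing the data, as were the scalings of the top quintile and of gene counts per list. No paired analysis was possible because the columns hold pooled values with no replicates. For the same reason count tests, fits of 4 libraries, leaving out single libraries, the check of 1 replicate against the other and set tests with an estimated correlation were not run, and depth is unknown. For counts the limit was a fixed ratio to the main count, and for other main results an interval that treats regions as independent. A value within its limit can still differ. By sum, 28437 regions were lower in formative DKO against WT, against 41479, which stayed within the limit although the higher share went from 22.3% to 42.1%. Of 154 alternative values of the main results, 101 stayed within their limits and 53 moved. Most are counts, which have no sign, and the median over all regions did turn: for formative DKO against WT from -0.63 to 0.10 with quantile normalization and 0.04 with loess offsets, for naive from -0.10 to 0.08 with quantile normalization and 0.12 by sum, and for the difference of the changes of state from -0.39 to 0.16 with quantile normalization. List medians had the main sign in 703 of 770 alternatives, which include value times width. Values of named regions were counted as moved in all 3318 alternatives by construction, since single regions have no interval. That count includes values equal to the main ones and says nothing about stability. Named regions were chosen for large folds, so their sign says little. No main result moved with value times width, without chromosomes 6 and 8, with pseudocounts of 0.1 and 5, with promoters within 1 kb or with genes within 25 kb. For value times width this was nearly fixed in advance, since the width cancels between groups within a region. For genes within 25 kb it holds for the totals over all lists. Of the 28 counts of genes with a risen or fallen region per list, 9 moved with genes within 25 kb. Where values moved, the cause was not tested.

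Formative DKO against WT gave 27540 higher and 24552 lower regions after quantile normalization, 19357 and 18078 with loess offsets, 23875 and 25107 after median centring, and 4126 and 63977 after scaling to promoters. Scaling to the sum gave 20645 higher. Naive DKO against WT gave 11223 and 42675 after scaling to promoters. Quantile normalization gave 32664 regions with a higher change of state in DKO. Among regions above the median of mean signal, higher and lower counts were 8723 and 9769 for naive DKO against WT, 4168 and 7451 for the change of state in DKO, and 11765 and 10971 for its difference from WT. Formative DKO was lower at 9469 there, and 7656 regions rose in WT. With an absolute log2 fold of at least 2 the counts were 7385 and 11610 for naive, 2598 and 18010 for formative DKO against WT, 5828 and 5826 for the change of state in DKO, and 8186 and 20982 for its difference from WT. Pooled WT values gave 40278 rising.

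Distal minus promoter medians in naive cells were -0.60 with quantile normalization, -0.55 with loess, -0.64 above the median signal and -0.66 with promoters within 2.5 kb. In formative cells they were -1.38, -0.66, -1.05 and -1.34, and -1.54 with no filter. The DKO over WT ratio of the change of state, 0.118 for rising and 0.297 for falling regions, was 0.153 and 0.185 with quantile normalization, 0.182 and 0.213 by sum, 0.156 and 0.262 by promoters, 0.200 and 0.199 with loess, 0.177 and 0.331 above the median signal, 0.176 and 0.213 with median centring, and 0.249 and 0.605 near genes chosen by RNA. With no filter it was 0.0992 for rising regions. The trophoblast list median turned from 1.61 to -0.17 with loess and -0.87 above the median signal for the change of state in WT, and from -1.02 to 0.27 with loess for DKO minus WT.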

Other observations

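The selection of genes by RNA and the choice of lists and of Gbx2 given here were made after the result was seen, and no difference here was tested. Over 634 genes with RNA at least 4-fold higher in formative WT in the authors' deposited table, the RNA medians were 2.72 in WT and 1.86 in DKO, and 79.0% were at least 2-fold higher in DKO. The DKO median was 68.3% of the WT median for RNA and 24.9% for H3K27ac at regions near these genes. Over 253 genes at least 4-fold lower, they were -2.56 and -0.72, and 39.9% were at least 2-fold lower in DKO. Here the DKO median was 28.0% of the WT median for RNA and 60.5% for H3K27ac. The H3K27ac percentages come from the main scaling alone, where medians over all regions were 0.48 in WT and -0.07 in DKO. For regions called in WT, the ratios of 0.118 for rising and 0.297 for falling regions became 0.176 and 0.213 with median centring. Whether the contrast between rising and falling genes holds in other scalings was not examined. The genes were chosen on WT RNA, which enlarges the WT RNA values, and the RNA libraries lie outside this series.

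RNA of lists of other lineages was higher in naive DKO than in naive WT cells in the authors' deposited table, with medians of 1.38 for primitive endoderm and 1.13 for trophoblast genes, over 8 genes each. H3K27ac medians of these lists were -0.02 and -0.04, with signs that changed with scaling. The germline and 2-cell-like list was at -2.70 by RNA, over 6 genes, and at -0.13 by H3K27ac, which was above 0 after quantile normalization or scaling to the sum. Gbx2 had RNA at -2.49 in WT and 3.15 in DKO for formative against naive cells in the authors' deposited table, with H3K27ac medians of 1.49 and 0.21.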
